A study of Mus musculus with 2 samples.

How the data were processed

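Tumors of a syngeneic fibrosarcoma implanted under the skin of wild-type C57BL/6 mice were minced, digested with collagenase and DNase for 45 min at 37 degrees C, filtered and freed of red cells, per the labels. Magnetic columns then gave an iron-positive eluate and an iron-negative flowthrough, and each fraction gave 1 library by the 10x Genomics 3' v3 protocol. The deposited matrices hold raw UMI counts per gene and barcode with no normalization, per the file headers and values. Reads were processed with Cell Ranger and the mm10 genome build, per the submitters' processing notes. The notes give Cell Ranger 3.1.0, while the file headers give 5.0.0, and which of them made the counts was not settled here. The annotation release is not given in the sources used here. Both deposited barcode lists had been filtered, since no barcode had under 500 UMIs.

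Of 32285 genes in the files, 32158 (99.6%) matched by Ensembl ID to the GENCODE annotation of the same build, which gave the coordinates. The iron-negative library had 10124 barcodes with a median of 12246.5 UMIs and 3387 genes, and the iron-positive library 13668 barcodes with a median of 6079 UMIs and 2111 genes. Cells were kept with at least 200 detected genes and at most 15% mitochondrial UMIs, which left 92.9% of the iron-negative and 88.8% of the iron-positive barcodes. Mitochondrial UMIs above the limit excluded 720 iron-negative barcodes and 1522 iron-positive barcodes, while 250 and 373 had too few genes, of which 249 and 370 were also above the mitochondrial limit. Doublets were called per library with Scrublet in scanpy at an expected rate of 0.08, and it marked 1 iron-negative and 2 iron-positive cells (0.0106% and 0.0165%). A caller that marks so few has not worked, so doublets remain among the kept cells, and an alternative removed the cells with the highest scores at 0.8% per 1000 barcodes.

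Both libraries were clustered together without batch correction, because a correction between them would remove the difference compared. Counts were scaled to 10000 per cell and log transformed, and 2000 variable genes, 30 principal components, 15 nearest neighbours, a shared-neighbour graph and Leiden clustering at resolution 1.0 with a fixed seed were used. The versions were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, leidenalg 0.10.2 and matplotlib 3.10.9. Clusters were named from marker lists fixed before the data were examined. The scoring rule was written afterwards, so the names are rebuilt names and stand for cells like the class. A cluster stayed unnamed when fewer than 3 markers were detected at 50 CPM, when its median UMIs were low with no marker of its class among its 10 leading genes, or when markers of another class led. T and NK cells were merged. Phagocyte clusters are also given by number.

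UMIs were summed over the cells of a class per library and given as CPM of the class total. Log2 ratios of iron-positive over iron-negative used each count plus 0.5. Lists of genes were fixed before the data were examined, and members with at least 10 CPM in either library were measured. Each list's median log2 ratio was placed as a percentile among 10000 random lists of the same size, matched on mean expression in 20 bins, and its interval came from 1000 Poisson draws of the counts. With 1 library per group there was no test, and the replicate check is missing for every value. Classes with at least 100 cells in both libraries were compared, which left the phagocytes, the mesenchymal class and all kept cells. A count of 0 in a library allowed a share of up to 0.0319% of iron-negative and 0.0247% of iron-positive cells, from 3 counts.

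Genes were named by a rule fixed beforehand. For phagocytes it took the 12 largest log2 ratios in each direction, and for the other comparisons the 5 largest, among genes with at least 50 CPM in the higher library and 100 UMIs in both together. Mitochondrial and ribosomal genes, numbered gene models and receptor segments were left out. To these it added the iron and heme genes at 10 CPM or more and up to 4 members of each other list. Genes of RNA quality, the mesenchymal markers of the matrix list and the genes given as cluster leaders were named after their values were seen. A few genes that the rule takes are not reported here.

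Alternatives fixed before the data were examined changed the mitochondrial limit to 10%, the gene minimum to 500, the doublet step, the resolution to 0.5 or 2.0 and the components to 15. Others used a mean of each cell's CPM, scaling by the median ratio over genes, thinning to 1000 UMIs per cell (which left out 89 iron-negative and 140 iron-positive phagocytes), subtraction of 10% free RNA, equal weights for clusters with at least 50 cells in both libraries, and list members at 50 CPM. Chosen after seeing the data were the removal of the highest doublet scores, classes for the low-UMI clusters, clustering without 33 of the 2000 variable genes that are iron, heme, NRF2, ferroptosis or named genes, and leaving out cluster 3. Also added then was a check of 7 genes within phagocyte clusters, which set the lower counting bound of the gain in UMIs per iron-positive cell against the upper bound of UMIs per cell in the lowest of 3 stromal classes.

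The ratio, interval and list steps were tested on simulated data drawn for all kept cells with 7901 genes at 10 CPM or more. For 50 genes at each true log2 ratio of -2, -1, 1 and 2, the median found was -2.01, -1.02, 0.98 and 1.98, and 96%, 100%, 98% and 90% of the intervals held the true value. Among 7701 unchanged genes 95.1% did. In the first form of the list check, 1 list of 15 unchanged genes with a median of -0.04 fell at percentile 0.33, which would have read as extreme. The check was then repeated, after that value was seen, with 200 such lists, of which 5% lay outside the central 95% of random lists, while 200 lists of genes raised 2-fold all lay above it. A percentile near 0 or 100 can thus go with a median close to 0, so each is given beside its median. The simulated genes were drawn independently from a pooled profile, with no shift in cluster makeup. The 5% therefore need not hold for lists of genes that vary together, for which extreme percentiles may be more common.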

Results

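Cells of a syngeneic fibrosarcoma, grown under the skin of wild-type C57BL/6 mice, were passed over a magnetic column. The column is meant to retain cells that hold enough iron (the iron-positive eluate) and to let the rest pass (the iron-negative flowthrough). The data hold no measure of iron, and retention for other reasons was not tested. Each fraction gave 1 single-cell RNA library, so every difference below is between 2 libraries, with no replicate check and no p-value. The iron-negative library held 10124 barcodes and 132796517 UMIs, and the iron-positive library held 13668 barcodes and 129921053 UMIs. After filtering, 9402 iron-negative cells with a median of 13018 UMIs and 12141 iron-positive cells with a median of 7349 UMIs were kept. Intervals are exact 95% intervals (binomial for shares, Poisson for UMI sums, and the matching interval for their ratio) and cover counting error only.

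The first comparison asked which cell classes each fraction holds. Mononuclear phagocyte-like cells, the class of monocytes and macrophages, were the largest class in both libraries, with 8818 of the iron-negative cells (93.8%, 93.3 to 94.3) and 8112 of the iron-positive cells (66.8%, 66.0 to 67.7). Endothelial-like cells, which line vessels, made up 3.44% (3.13 to 3.78) of the iron-positive and 0.0957% (0.0438 to 0.182) of the iron-negative cells, a ratio of 36.0 (18.8 to 79.2). Pericyte-like or smooth muscle-like cells, which wrap vessels, numbered 161 in the iron-positive library (1.33%, 1.13 to 1.55) and 1 in the iron-negative library (0.0106%, 0.000269 to 0.0592). Mesenchymal-like cells, a class in which fibroblasts and fibrosarcoma cells were not told apart, made up 3.79% (3.46 to 4.14) against 1.57% (1.33 to 1.85), a ratio of 2.41 (1.996 to 2.92). Of these, 218 and 87 cells were in cluster 14, whose marker score was 0.298 for this class and 0.231 for mononuclear phagocytes. The ratio was 17.5 (8.29 to 44.2) in cluster 16 of this class and 1.20 (0.846 to 1.73) in cluster 18. T or NK-like cells made up 0.799% (0.648 to 0.974) against 0.372% (0.259 to 0.517), a ratio of 2.15 (1.44 to 3.26), and were named in 4 of 9 alternatives.

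Clusters that stayed unnamed held 23.8% (23.1 to 24.6) of the iron-positive and 4.16% (3.76 to 4.58) of the iron-negative cells. Most were in 3 clusters of few UMIs. Cluster 4, with Wfdc17, Mmp12 and Prdx1 among its leading genes and a median of 968.5 UMIs, held 13.4% (12.8 to 14.0) of the iron-positive and 0.872% (0.694 to 1.08) of the iron-negative cells. Cluster 11, led by Gzma, Ubd and Ctla2a with a median of 1062 UMIs, held 5.21% (4.82 to 5.62) against 0.255% (0.164 to 0.380). Cluster 10, led by the ribosomal RNA-derived transcript Gm42418 with a median of 841 UMIs, held 4.17% (3.82 to 4.54) against 2.75% (2.43 to 3.11). Cluster 20 mixed neutrophil and mast cell genes such as S100a9 and Cma1 (0.675% against 0.170%), cluster 21 mixed B cell and plasmacytoid dendritic cell genes such as Cd79a and Siglech (0.255% against 0.0213%), and cluster 22 was led by the osteoclast genes Ctsk and Acp5 (0.107% against 0.0851%). The column and the depth gap can both set these shares, since cells of the iron-positive library held fewer UMIs. With the low-UMI clusters given the class that their markers ranked first, the log2 ratio of the phagocyte shares was -0.21, against -0.49 with those clusters unnamed.

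**Figure D1:**
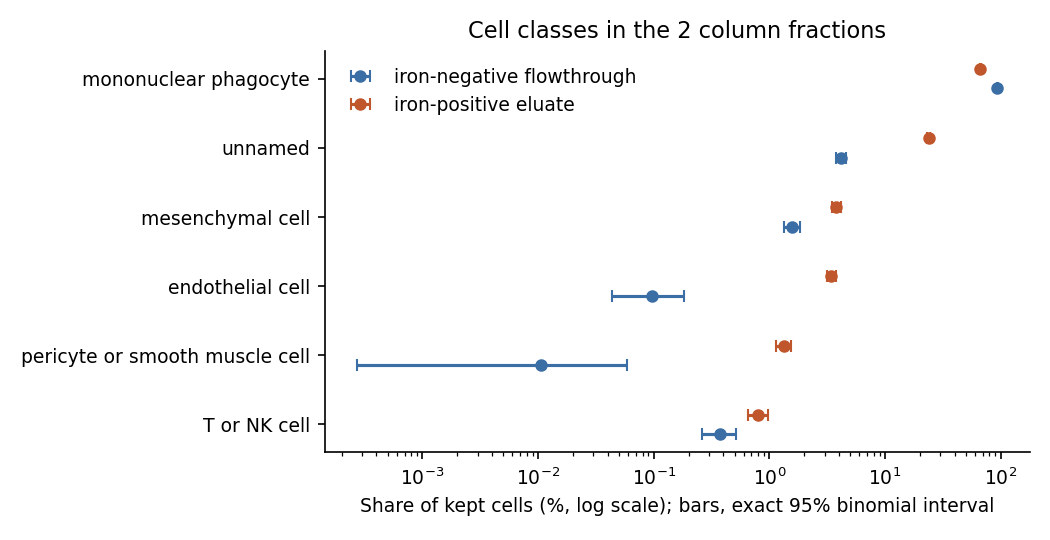
Share of kept cells in each cell class (percent, log scale) in the iron-negative flowthrough and the iron-positive eluate, 1 library each, with bars for the exact 95% binomial interval. Endothelial-like cells stand at 0.0957% and 3.44%, and mononuclear phagocyte-like cells at 93.8% and 66.8%.

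The main comparison of expression was within the mononuclear phagocyte-like cells, which take up dying red cells and recycle their iron. Among genes with at least 50 CPM in the higher library, the largest ratio was that of Slc40a1, which encodes ferroportin, the iron exporter, at 104 CPM in the iron-positive against 5.60 CPM in the iron-negative phagocytes (18.5-fold higher, log2 ratio 4.21, 4.10 to 4.33). Hmox1, which encodes the enzyme that opens heme and frees its iron, was 4.19-fold higher (1654 against 394 CPM, log2 ratio 2.07, 2.05 to 2.08). Genes for the matrix protease Mmp12 (13.2-fold), the lipid scavenger receptor Cd36 (7.90-fold), the glycoprotein Gpnmb (7.36-fold) and the hemoglobin scavenger receptor Cd163 (3.85-fold) were higher in the iron-positive phagocytes too. Fcrls, an Fc receptor-like gene, was 2.36-fold lower (80.4 against 190.1 CPM), and the fractalkine receptor gene Cx3cr1 was 1.81-fold lower (149 against 269 CPM). With each phagocyte cluster weighted equally in both libraries, the log2 ratios were 2.63 for Slc40a1, 0.54 for Hmox1, 1.48 for Mmp12, 1.25 for Cd36, 1.67 for Gpnmb, 0.71 for Cd163 and -0.21 for Cx3cr1. The sums rest on 89544271 iron-positive and 124088557 iron-negative UMIs, with medians of 9906.5 and 13426 UMIs per phagocyte.

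The other genes named by size among those higher in the iron-positive phagocytes were Cxcl3, a chemokine for neutrophils (5.28-fold), the antiprotease gene Slpi (4.80-fold), Gclm, a subunit gene of the enzyme that starts glutathione synthesis (4.57-fold), the ubiquitin ligase gene Rnf128 (4.51-fold), the metallothionein gene Mt2 (4.13-fold) and the glutathione transferase gene Gstm1 (3.93-fold). On the lower side stood Retnla (2.02-fold), the histone gene Hist1h2ap (1.99-fold), Gatm of creatine synthesis (1.84-fold), the cyclooxygenase gene Ptgs1 (1.76-fold), Olfml3 (1.70-fold), Pmepa1 (1.68-fold), the scavenger receptor gene Stab1 (1.64-fold), the adhesion genes F11r (1.63-fold) and Vcam1 (1.60-fold), and the creatine kinase gene Ckb (1.59-fold). With clusters weighted equally, Slpi turned to a log2 ratio of -0.14 and Cxcl3 stood at 0.18 (0.54 without cluster 3). In the same weighting Rnf128 stood at 0.72, Mt2 at 0.79, Gclm at 0.87, Gstm1 at 0.87 and Retnla at -1.65. Hist1h2ap and Gstm1 belong to families of near copies, so their counts are uncertain. In the annotation of the mm10 build, Slc40a1 lies on chromosome 1 at 45908068 to 45926523 (minus strand), Hmox1 on chromosome 8 at 75093621 to 75100589 (plus strand) and Mmp12 on chromosome 9 at 7344381 to 7369499 (plus strand), all as protein-coding genes.

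Iron and heme genes were of particular interest because the column is meant to separate by iron, and single genes stood far above the lists they belong to. Of the 34 measured genes of the 3 iron and heme lists, 11 were higher and 23 lower in the iron-positive phagocytes, 7 of them higher by at least 1.5-fold and 0 lower by as much. The median log2 ratio was -0.12 (-0.13 to -0.08), which is percentile 19.1 of random lists matched on expression, while the median over all 7722 measured genes was -0.10. Beside Slc40a1, Hmox1 and Cd163, the higher genes were the heme transporter gene Slc48a1 (log2 ratio 1.30), the mitochondrial iron importer gene Slc25a37 (1.02), the iron-sensing ubiquitin ligase gene Fbxl5 (0.77), the ferritin chains Ftl1 (0.68; 9031 against 5631 CPM) and Fth1 (0.57; 23921 against 16135 CPM), the ferritin turnover receptor gene Ncoa4 (0.30), the biliverdin reductase gene Blvrb (0.29) and Slc11a1 (0.12). With clusters weighted equally Fbxl5 stood at -0.07, Slc11a1 at -0.09, Slc48a1 at 0.45 and Slc25a37 at 0.30. Ftl1 and Fth1 have near copies elsewhere in the genome, so reads could be split between them.

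The remaining iron and heme genes reported here lay between -0.44 and -0.00. Hfe, which regulates iron uptake, was at -0.44, the mitochondrial importer Slc25a28 at -0.35, the transporter Slc11a2 at -0.29 and Alas1, which starts heme synthesis, at -0.23. Near the median of all genes were Urod (-0.20), Pcbp1 (-0.19), Steap3 (-0.19), Aco1 (-0.19), Bach1 (-0.17), Slc39a14 (-0.17), Blvra (-0.17), Ireb2 (-0.15), Fech (-0.14), Cpox (-0.14), Alad (-0.14), Lrp1 (-0.13), the transferrin receptor gene Tfrc (-0.12), Cp (-0.11) and Trf (-0.11). Tfrc stood at 0.13 with each cell thinned to 1000 UMIs, and Cp at 0.16 without cluster 3. Hmox2 (-0.04), Pcbp2 (-0.00) and Flvcr1 (-0.00) had intervals that held 0. By list, iron import and heme uptake had a median of -0.12 (9 genes, percentile 37.5; 0.12 among members at 50 CPM or more), iron storage, export and regulation -0.00 (14 genes, percentile 95.9; 0.28 among members at 50 CPM or more and -0.09 with clusters weighted equally), and heme breakdown and synthesis -0.14 (11 genes, percentile 22.5). The joined median was 0.06 among members at 50 CPM or more.

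Targets of NRF2, the transcription factor that answers oxidative and heme stress, were higher as a group. Of 15 measured targets, 14 were higher, 9 of them by at least 1.5-fold, and the median log2 ratio was 0.67 (0.65 to 0.69), at percentile 100 of random lists. Gsr, the glutathione reductase gene, was 3.01-fold higher (85.6 against 28.5 CPM), the peroxidase gene Prdx1 2.83-fold higher (2324 against 820.1 CPM), and Gclc, the catalytic partner of Gclm, 2.17-fold higher. Tkt of the pentose phosphate pathway was the 1 target below 0 (-0.13). The median was 0.31 without phagocyte cluster 3 and 0.17 with each phagocyte cluster weighted equally.

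**Figure D2:**
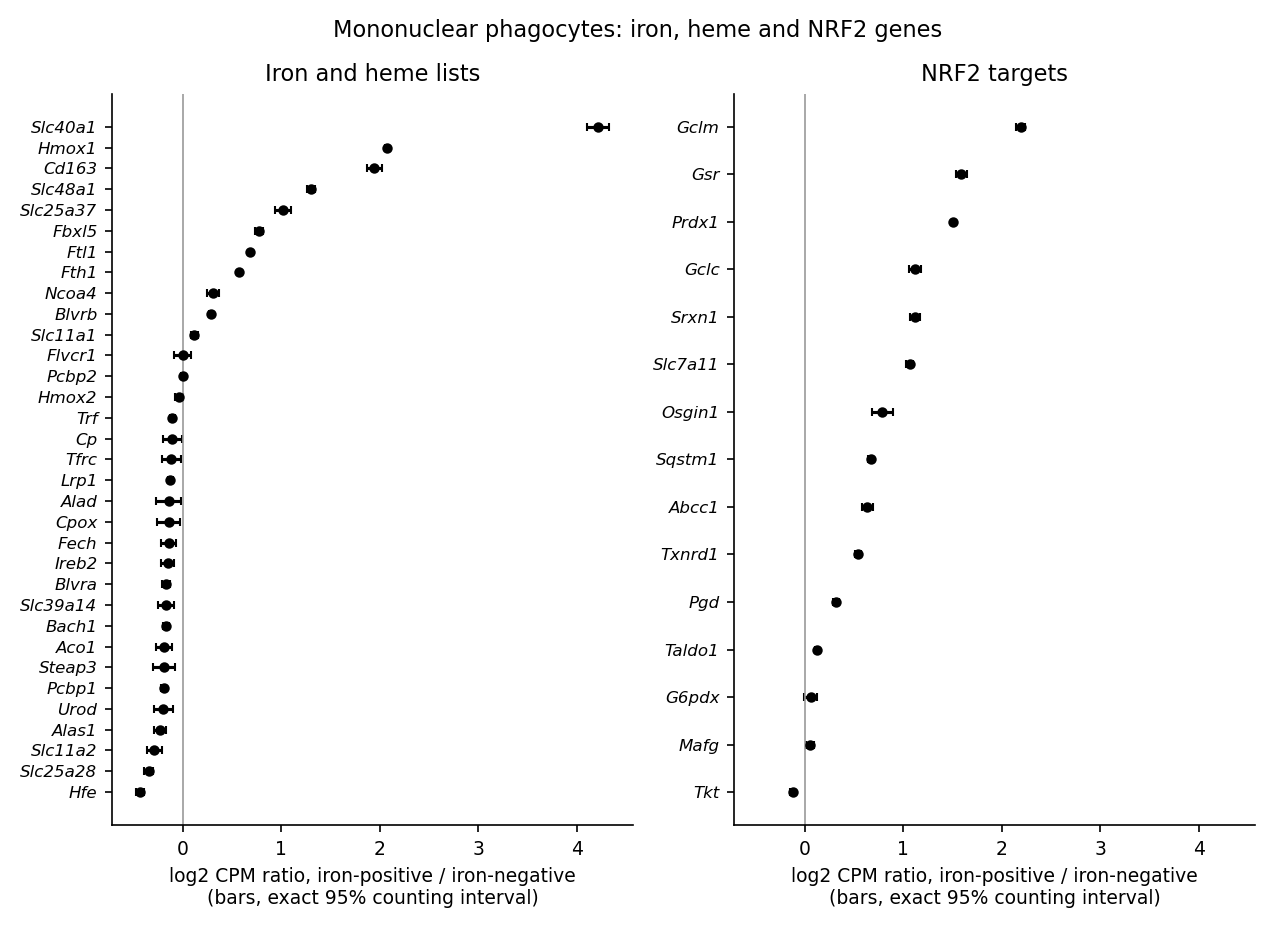
Log2 ratio of CPM, iron-positive over iron-negative, of the measured iron, heme and NRF2 genes reported here in the mononuclear phagocyte-like cells of 1 library per group, with bars for the exact 95% counting interval. Iron and heme genes run from Hfe (-0.44) to Slc40a1 (4.21) and NRF2 targets from Tkt (-0.13) to Gclm (2.19), and of the iron and heme genes, Fbxl5, Slc11a1, Tfrc and Cp changed sign in an alternative, as did Hmox2, Pcbp2 and Flvcr1, whose intervals held 0.

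The phagocytes of the 2 fractions were spread over different clusters. Cluster 3, with Mmp12, Cxcl3, Cd36, Hmox1 and Slc40a1 among its leading genes, held 21.1% (20.2 to 22.0) of the iron-positive and 2.02% (1.74 to 2.33) of the iron-negative phagocytes. Those genes take part in its definition, so cells were clustered again without the iron, heme, NRF2, ferroptosis and named genes. The cluster that then held 92.4% of the cells of cluster 3 made up 16.6% (16.0 to 17.3) of all iron-positive and 2.60% (2.28 to 2.94) of all iron-negative cells, a ratio of 6.41 (5.61 to 7.35), with Hmox1 at 3986 CPM. A cluster led by the lectin genes Cd209f and Cd209g and by Marco and Cd163 made up 7.12% (6.67 to 7.59) against 2.30% (2.004 to 2.62), a ratio of 3.098 (2.67 to 3.61). The cluster led by the antigen presentation genes H2-Eb1 and H2-Aa made up 7.85% (7.38 to 8.34) against 21.4% (20.6 to 22.2), a ratio of 0.367 (0.339 to 0.396), and that led by Fcrls and Cbr2 had a ratio of 0.422 (0.387 to 0.461). As shares of all kept cells, cluster 3 itself had a ratio of 7.46 (6.39 to 8.75). The cluster that matched it best had a ratio of 4.17 at a Leiden resolution of 0.5 and of 25.8 at 2.0, where the cells common to both were 45.3% of the cells in either.

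Comparisons within single clusters take out shifts between clusters but not shifts inside one, and 10 phagocyte clusters had at least 50 cells in both libraries. In the clustering without iron genes, Retnla and Marco, leading genes of cluster 2, led different clusters. These had share ratios of 0.471 and 3.098 and Slc40a1 at 71.5 and 211 CPM, so a shift inside cluster 2 stays possible. Against all other cells, clusters 3, 8 and 15 had 1 marker of another class and 0 of their own among their 10 leading genes, although against cells of other classes each had at least as many of its own, so genes are given here by cluster number. Slc40a1 was higher in the iron-positive cells in 10 of 10 clusters, each with an interval above a ratio of 1, and the ratio was 11.1 (9.66 to 12.8) in cluster 2 and 5.30 (4.39 to 6.53) in cluster 3. Hmox1 was higher in 9 of 10, with a ratio of 1.37 in cluster 3 (4968 against 3620 CPM) and 0.949 (0.884 to 1.02) in cluster 6, the exception. Fth1, Mmp12, Cd36 and Gpnmb were each higher in 10 of 10 clusters with intervals above 1. Free RNA enters all droplets of a library, so each gain in UMIs per cell was set against the level in the stromal class with the least. For Slc40a1 that level was 0.0621 UMIs per pericyte-like cell, and the gain lay above it, beyond counting error, in clusters 2, 3, 5 and 7, with 2.02 UMIs per cell in cluster 2 and 2.42 in cluster 3. Hmox1 passed its level (2.07) in the same clusters, Fth1 (54.9) and Cd36 (0.373) in clusters 2, 3 and 7, Mmp12 (1.24, in endothelial-like cells) in clusters 0, 3, 5 and 7, and Gpnmb (0.0497) in 6 clusters. In the other clusters the gains of these genes cannot be told from free RNA. The NRF2 targets had a median above 0 in 8 of 10 clusters (-0.06 to 0.34), a count not set against free RNA. That count does not set them apart, since ribosomal proteins had 10 of 10, oxidative phosphorylation 9 and chemokines 8. The MHC class II list had a median above 0 in 2 of 10, and its gene H2-Aa was higher in 1 of 10. The log2 ratio of H2-Aa was -1.66 in cluster 3 and -1.29 in cluster 2, but -0.08 in cluster 0 and -0.02 in cluster 1.

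**Figure D3:**
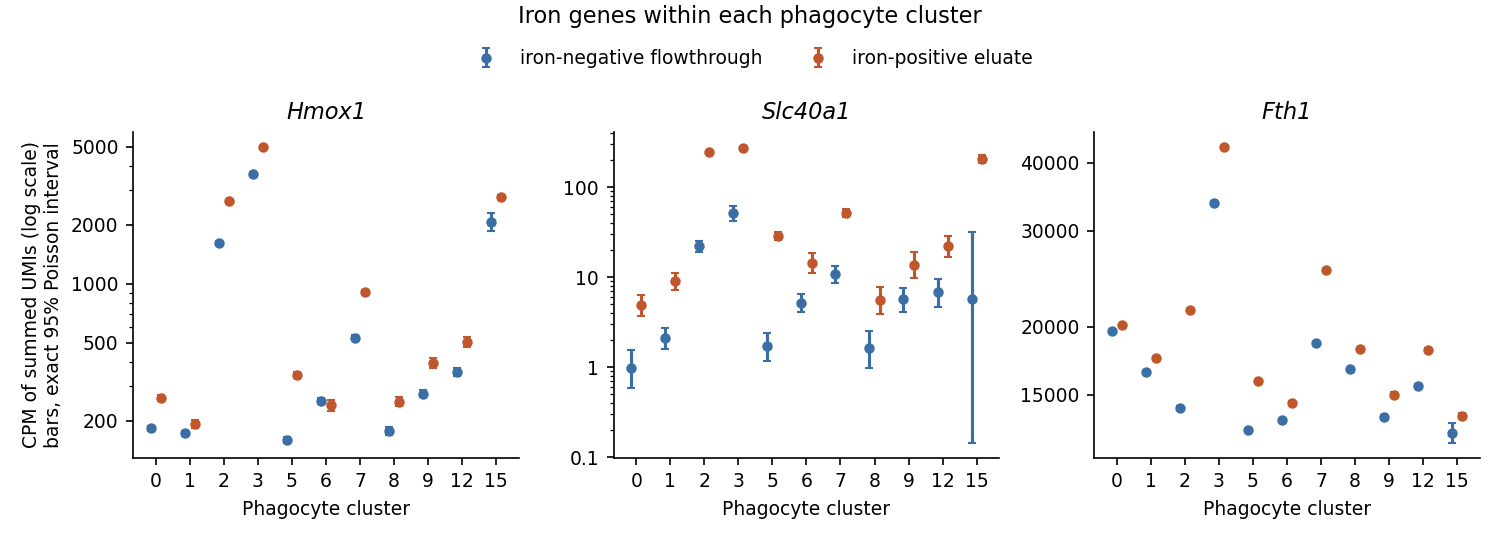
CPM of summed UMIs (log scale) of Hmox1, Slc40a1 and Fth1 in each phagocyte cluster of the iron-negative flowthrough and the iron-positive eluate, 1 library each, with bars for the exact 95% Poisson interval. Hmox1 was highest in cluster 3, at 4968 and 3620 CPM, and Slc40a1 was higher in the iron-positive cells of each cluster with at least 50 cells in both libraries, by more than its level in pericyte-like cells in clusters 2, 3, 5 and 7.

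Gene lists beyond iron also separated the phagocytes of the 2 fractions. Matrix and matrix remodelling genes were higher in 13 of 14 (median log2 ratio 1.23, percentile 100; 0.64 with clusters weighted equally, 0.62 without cluster 3 and 0.62 among members at 50 CPM or more), among them Mmp12, Spp1 (osteopontin, 1.52) and the collagenase gene Mmp13 (0.94). The higher members also included the mesenchymal markers Sparc (3.02), Col1a1 (2.27), Col3a1 (1.99) and Col1a2 (1.74), at 17.1 to 49.7 CPM in the iron-positive phagocytes. Mesenchymal-like cells were 2.41 times as frequent in that library, and the mesenchymal cluster led by Col1a1 (cluster 16) 17.5 times. After subtracting 10% free RNA the median of the matrix list was 0.47. That median was above 0 in 10 of 10 phagocyte clusters (0.49 to 0.90), and how much of it is free RNA was not tested. Hypoxia genes were higher in 15 of 17 (0.55, percentile 100; 0.05 with clusters weighted equally), among them Ero1l (0.99) and the mitophagy gene Bnip3 (0.83). Lipid-associated macrophage genes were higher in 12 of 16 (0.32, percentile 100; 0.08 with clusters weighted equally), with Cd9 at 1.09. Chemokine genes were higher in 12 of 17 (0.26, percentile 100; 0.08 in that weighting), with Ccl6 at 0.99 and Ccl3 at 0.94. Ferroptosis defence and glutathione genes were higher in 12 of 14 (0.18, percentile 100; 0.03 in that weighting), with the peroxiredoxin gene Prdx6 at 1.33, the cystine carrier gene Slc7a11 at 1.06 and the catalase gene Cat at 0.92. MHC class II genes were lower in 8 of 9 (-0.47, percentile 0; -0.12 in that weighting), with H2-Eb1 at 1772 against 2742 CPM and Cd74 at 6525 against 9297 CPM.

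Several lists had medians above 0 that changed sign in at least 1 alternative. M2-type and resident macrophage genes had a median of 0.30 (12 of 18 higher, percentile 100), with Igf1 at 1.26 and the transglutaminase gene F13a1 at 1.07, but -0.04 with clusters weighted equally and a median above 0 in 0 of 10 clusters. Endothelin and angiogenesis genes had 0.20 (8 of 12, percentile 100; -0.03 with clusters weighted equally and -0.27 after subtracting 10% free RNA), while the endothelin receptor gene Ednrb was itself at 1.53 (50.2 against 17.3 CPM). Within clusters, Ednrb was higher in the iron-positive cells in 10 of 10, and 8 had an interval above a ratio of 1. The ratio was smallest in cluster 2, at 1.18 (217 against 184.5 CPM), and was 1.74 (1.33 to 2.35) in cluster 3. Pericyte-like cells of the iron-positive library held 674 CPM. The gain of Ednrb passed the lowest stromal level (0.722 UMIs per cell) in 0 of 10 clusters. That count cannot decide, because iron-positive cells of every cluster but cluster 2 held fewer Ednrb UMIs than that level (0.510 per cell in cluster 3). Glycolysis genes had 0.15 (13 of 14, percentile 99.99; -0.13 with clusters weighted equally), with the glucose carrier gene Slc2a1 at 0.55. Efferocytosis and scavenger receptor genes had 0.08 (6 of 12, percentile 99.9; -0.00 after thinning), with Axl at -0.55. T cell cytotoxicity and exhaustion genes, of which 4 were measured, had 0.17 (percentile 98.7; -0.17 with clusters weighted equally), with Ccl5 at 0.50.

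The remaining lists lay close to the median of all genes or below it. Interferon response genes had a median of 0.04 (12 of 19 higher, percentile 99.9), with Rsad2 at 0.74. Immediate early and dissociation stress genes had 0.04 (11 of 19, percentile 98.8; -0.06 with clusters weighted equally), with Egr1 at 0.58. Lysosome genes had 0.03 (13 of 24, percentile 98.5; -0.05 with clusters weighted equally), with the protease gene Ctsd at 0.82. Oxidative phosphorylation genes had 0.00 (11 of 21, percentile 92.5; -0.02 after subtracting 10% free RNA), with Atp5a1 at -0.31, and M1-type and inflammatory cytokine genes -0.01 (5 of 11, percentile 88.9; 0.07 without cluster 3), with Nos2 at 0.82 and Cxcl9 at -0.35. Ribosomal protein genes had -0.01 (10 of 22, percentile 61.1; 0.07 when scaled by the median ratio of genes), with Rps2 at 0.22. Complement genes had -0.10 (5 of 12, percentile 27.9), with C1qb at -0.32, and MHC class I genes -0.11 (1 of 11, percentile 21.4), with Psmb10 at -0.28. Unfolded protein response genes had -0.13 (1 of 9, percentile 19.5), with Herpud1 at -0.37, and immune checkpoint and regulatory ligand genes -0.18 (5 of 14, percentile 1.96), with Pdcd1lg2 at -0.53 and Cd274 at 0.48. Cell cycle genes had -0.22 (1 of 19, percentile 0.06; 0.02 without cluster 3), with Mki67 at -0.27. None of the 5 red cell transcripts reached 10 CPM in phagocytes.

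**Figure D4:**
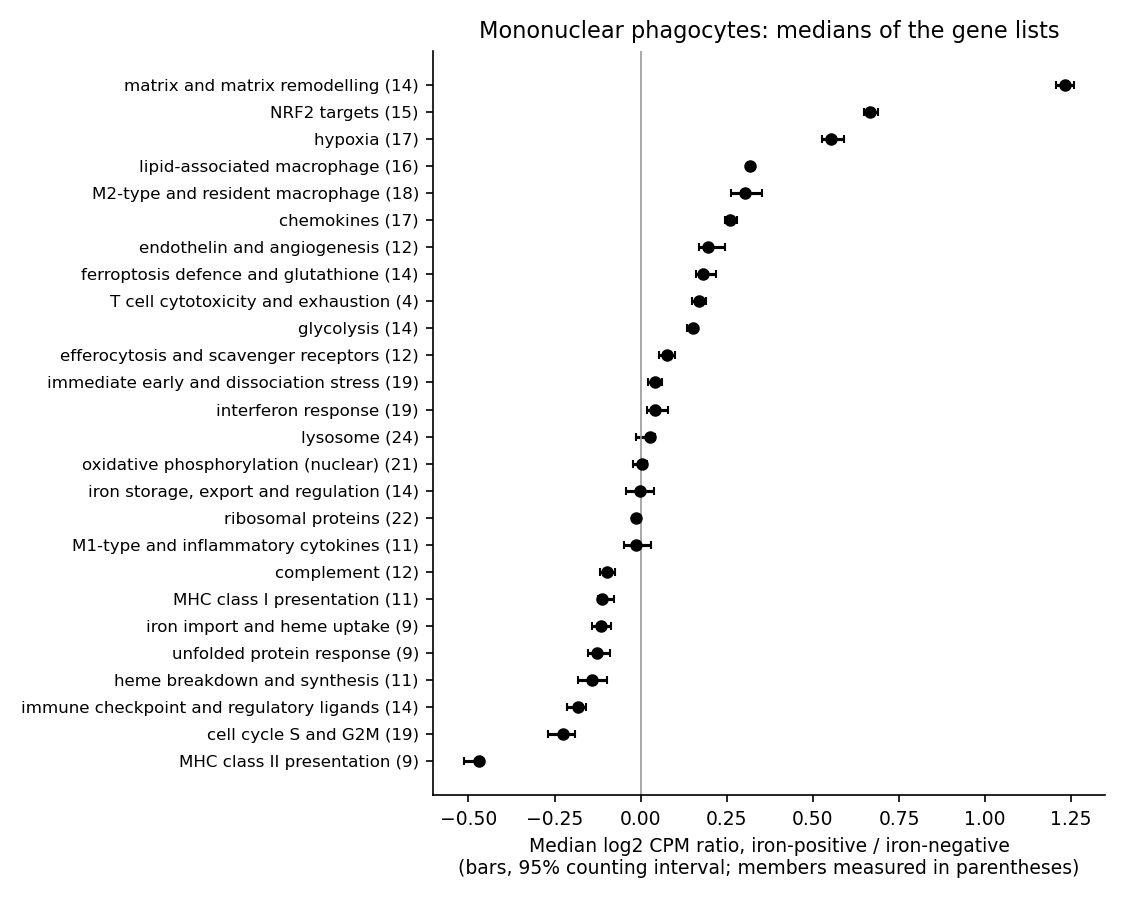
Median log2 ratio of CPM, iron-positive over iron-negative, of each gene list in the mononuclear phagocyte-like cells of 1 library per group, with bars for the 95% counting interval and the number of measured members in parentheses. Medians run from -0.47 for MHC class II presentation to 1.23 for matrix and matrix remodelling, and that of ribosomal proteins (-0.01) was 0.07 when scaled by the median ratio.

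Signs of RNA quality differed between the phagocytes of the 2 libraries. Gm42418 was 2.13-fold higher in the iron-positive phagocytes (21806 against 10256 CPM), AY036118, another ribosomal RNA-derived transcript, 1.86-fold higher, and the nuclear RNA Malat1 1.27-fold higher. The hemoglobin gene Hbb-bs had 109 UMIs in the iron-positive and 4 in the iron-negative phagocytes. Cluster 9, led by the heat shock genes Hspa1b and Hspa1a, held 3.44% (3.05 to 3.86) of the iron-positive and 6.11% (5.62 to 6.63) of the iron-negative phagocytes.

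Over all kept cells, where makeup and expression both enter, vessel genes differed most between the fractions. The pericyte gene Rgs5 was 78.2-fold higher in the iron-positive library (155 against 1.98 CPM), the fatty acid carrier gene Fabp4 43.3-fold, the endothelial junction gene Cldn5 36.7-fold, Myct1 36.2-fold and the adhesion gene Mcam 36.1-fold. As a mean of each cell's CPM, the log2 ratio was 4.85 for Fabp4, against 5.44, and 5.86 for Myct1, against 5.18. Lower were Fcrls (3.01-fold), Retnla (2.60-fold), Gatm (2.35-fold), Cx3cr1 (2.31-fold) and Ptgs1 (2.19-fold). Matrix genes were higher in 19 of 22 (median log2 ratio 2.25), endothelin and angiogenesis genes in 13 of 16 (1.16) and NRF2 targets in 11 of 15 (0.60). MHC class II genes were lower in 9 of 9 (-0.79) and complement genes in 10 of 14 (-0.34), and the joined iron and heme lists had a median of -0.15. The median log2 ratio of 2811 genes at 50 CPM or more in both libraries was -0.10, and scaling by it turned the M1-type and inflammatory cytokine median from -0.06 to 0.04.

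Among the mesenchymal-like cells, 460 iron-positive cells were set against 148 iron-negative cells. In 6 of 9 alternatives the class held 63 to 67 iron-negative cells, fewer than the 100 that a comparison required, and expression in the class was not recomputed with other clusterings or cell filters. Cfd, which encodes adipsin, had 648 UMIs in the iron-positive cells and 0 in the iron-negative cells, which is at least 93.3-fold higher than a floor of 3 counts over the class. Rgs5 had 1088 against 2 UMIs, a ratio of 188 (log2 ratio 7.55, 6.02 to 10.92, but 2.62 as a mean of each cell's CPM), Hbb-bs 1262 against 6 UMIs and the imprinted gene Mest 1101 against 13 UMIs. Lower in the iron-positive cells were the natriuretic peptide gene Nppb (5.55-fold), the mesothelin gene Msln (5.54-fold), the chromatin gene Hmga1 (4.34-fold), Klra4 (4.07-fold) and the lubricin gene Prg4 (3.85-fold). Interferon response genes were higher in 15 of 19 (median 0.46), endothelin and angiogenesis genes in 15 of 18 (0.92) and matrix genes in 19 of 21 (0.80), while glycolysis genes were lower in 11 of 14 (-0.44) and MHC class II genes in 7 of 7 (-0.84, or -1.43 as a mean of each cell's CPM).

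NRF2 targets in the mesenchymal-like cells had a median of -0.00, with 7 of 15 higher, and the joined iron and heme lists had -0.17. The makeup of the class by cluster differed between the 2 libraries. Cluster 14, with Cfd, Dpt and Pi16 among its leading genes and a median of 1914 UMIs, had 218 iron-positive and 87 iron-negative cells. As shares of all kept cells this was a ratio of 1.94 (1.51 to 2.52). Cfd had 0 UMIs in the iron-negative cells of the class, so it led the cluster through iron-positive cells alone. Prg4, another leading gene, was 3.85-fold lower in the iron-positive cells of the class. The cluster may thus hold unlike cells in the 2 libraries. Cluster 16, led by the collagen gene Col1a1 and by Tnc, had 158 and 7, a ratio of shares of 17.5 (8.29 to 44.2). Cluster 18, led by Sox9 and Grem1, had 84 and 54, a ratio of 1.20 (0.846 to 1.73), whose interval held 1. The 4 measured red cell transcripts had a median of 5.46, but -1.84 as a mean of each cell's CPM, and Hbb-bs in that measure stood at -1.74.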

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

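Hmox1 in the barcodes left out was looked at only after its values in the kept phagocytes were seen. The share of deposited barcodes with over 15% mitochondrial UMIs, which entered no comparison, was 11.1% (10.6 to 11.7) in the iron-positive and 7.11% (6.62 to 7.63) in the iron-negative library. Among the UMIs of those barcodes that were not mitochondrial, Hmox1 stood at 1418 CPM (1364 to 1472) over 1522 iron-positive barcodes and at 352 CPM (310 to 399) over 720 iron-negative barcodes, with median depths of 2136.5 and 1905.5 UMIs. Both drew attention because the level in the iron-positive library lay above that in the flowthrough, in barcodes outside the main measurement.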

How the results depend on the processing

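Chosen after seeing the data were the removal of the highest doublet scores, classes for low-UMI clusters, clustering without iron genes and leaving out cluster 3. Values are log2 ratios of iron-positive over iron-negative, and the cause was not tested for any that moved or reversed. The endothelial share stayed between 4.61 and 5.28 and the pericyte share between 6.14 and 6.99 over 9 alternatives. T or NK cells were named in 4 of them (0.84 to 1.10), and the others gave no value. In phagocytes Slc40a1 (2.63 to 4.29), Hmox1 (0.54 to 2.15), Fth1 (0.25 to 0.65) and Mmp12 (1.48 to 3.80) kept their direction over 13 alternatives, and matrix genes (0.47 to 1.31) and MHC class II genes (-0.52 to -0.12) over 14. The share of the cluster matching cluster 3 (2.90) was 3.35 at 10% mitochondrial UMIs, 2.06 at resolution 0.5, 4.69 at 2.0 and 3.45 without the highest doublet scores. The phagocyte share (-0.49) was -0.35 with at least 500 genes, -0.40 at resolution 2.0 and -0.21 with low-UMI clusters given a class. The mesenchymal share (1.27) was 1.60 with called doublets kept and 1.60 at resolution 2.0. The joined iron and heme median of phagocytes (-0.12) was -0.13 with low-UMI clusters given a class, -0.14 by mean CPM per cell, -0.042 by median-ratio scaling, -0.081 without cluster 3 and reversed to 0.057 among members at 50 CPM. That of all kept cells (-0.15) was -0.047 by median-ratio scaling, and that of mesenchymal cells (-0.17) was -0.23 after free RNA subtraction. The NRF2 median (0.67) was 0.63 by mean CPM per cell, 0.75 by median-ratio scaling, 0.58 after thinning, 0.17 with equal cluster weights and 0.31 without cluster 3. Over 153 other results and 1246 values, 1183 kept their sign, 26 reversed, and 37 changed sign where the interval of the value as reported held 0. Counted by size, 390 of the 1246 moved outside the interval of the value as reported without reversing, and 830 stayed inside it. By median-ratio scaling, ribosomal proteins reversed to 0.069, and M1-type genes of all kept cells to 0.040. After thinning, efferocytosis was -0.00028 and Tfrc 0.13. After free RNA subtraction, endothelin and angiogenesis was -0.27, dissociation stress -0.0058 and mesenchymal chemokines -0.23. With equal cluster weights, M2-type genes were -0.044, glycolysis -0.13, endothelin and angiogenesis -0.030, dissociation stress -0.056, ribosomal proteins 0.090, T cell cytotoxicity -0.17, Fbxl5 -0.072, Slc11a1 -0.090 and Slpi -0.14. Among members at 50 CPM, iron import was 0.12 and T cell cytotoxicity -0.16. Without cluster 3, glycolysis was -0.013, cell cycle 0.016, ribosomal proteins 0.0065, Cp 0.16, Slc11a1 -0.060 and Tfrc 0.027. By mean CPM per cell, mesenchymal red cell transcripts were -1.84 and Hbb-bs -1.74. No paired analysis was possible because each group has 1 library, which also rules out leaving out a replicate. The number of cells, not depth, limits the endothelial and pericyte classes, with 9 and 1 iron-negative cells.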

Other observations

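Of the tests reported here, those of depth and cluster makeup on the NRF2 list, all tests of free RNA in phagocytes and all tests on the stromal cells were chosen after results were seen, and the criteria for free RNA and for shared droplets were revised in that light. The planned tests of depth and cluster makeup on the joined iron and heme lists turned out void, because the median they were to explain lay below 0. The tests of cluster 4 were fixed beforehand.

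Iron, heme and NRF2 genes in phagocytes differed between the fractions, and depth, cluster makeup and free RNA were weighed, while the iron load of the cells, the difference the design names, stays open as untested. On the joined lists the median was -0.12 after thinning to 1000 UMIs and -0.10 with clusters weighted equally, and neither value can decide. The NRF2 median was 0.58 after thinning, against 0.67, which argues against the greater weight of deep cells in the sums as the whole cause. Thinning keeps the expected proportions of each cell, so it cannot decide on other effects that go with low depth. With equal weights over 11 clusters made without these genes the NRF2 median was 0.23, so much of it may come from which phagocytes the column holds back. In that weighting Hmox1 (0.59) and Slc40a1 (2.57) stayed above 0, and 12 of 15 targets were higher. For Hmox1, the UMIs per cell in pericyte-like cells of the iron-positive library, whose droplets hold the same free RNA, came to 14.9% of the gain per phagocyte, which argues against free RNA as its source, but over 16 genes the median was 62.4%, so that for those genes as a set free RNA cannot be told apart from a gain in the phagocytes, because stromal cells may express the genes themselves.

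Endothelial-like, pericyte-like and mesenchymal-like cells were more frequent in the iron-positive library as classes, although mesenchymal cluster 18 had a ratio of 1.20 (0.846 to 1.73). Phagocytes in the same droplets and iron of the cells' own were weighed as causes. Over 17 abundant phagocyte markers the median level was at most 17.3% of the phagocytes' level in endothelial-like and pericyte-like cells, while phagocytes in 94.7% and 95.5% of the droplets would be needed, which argues against shared droplets as the whole cause there. In mesenchymal-like cells it was 23.5% (quartiles 21.8 to 25.1), while 49.9% would be needed, which argues against shared droplets as the whole cause, and a part of the excess stays open. By an earlier criterion, an upper quartile below 24.9% (0.5 times that share), the mesenchymal test had stayed open. Iron of the cells' own stays open, because only 9 endothelial-like and 1 pericyte-like cells were in the iron-negative library, and because the joined iron and heme median of mesenchymal-like cells (-0.17) is of transcripts, which do not measure iron. Retention of stromal cells on the column for reasons other than iron was not tested and stays open too.

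The low-UMI cluster 4 lay mostly in the iron-positive library. Its profile over variable genes, which are not independent replicates, was correlated by rank with those of 11 phagocyte clusters. The highest correlation was with cluster 3 (rho 0.86), with cluster 2 close behind (0.85). Of the leading genes of cluster 4, Mmp12 and Mmp8 also led cluster 3, while Saa3 and Marco also led cluster 2. It may thus hold RNA-poor droplets of cells like those of cluster 3, of cluster 2 or of both. For 20 leading genes of cluster 3, cluster 4 stood at a median log2 ratio of 0.87 over the mean profile of the library. That mean stood in for free RNA, whose own profile could not be measured because no barcode had under 500 UMIs. The test therefore cannot decide on free RNA. A biological state of few transcripts was not tested.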
